A study of Mus musculus with 38 samples.

How the data were processed

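The series holds 29 RNA-seq and 9 ATAC-seq libraries from Tcf21 lineage cells of mouse visceral adipose tissue. Per the labels, the cells were sorted by flow cytometry and 5000 cells went into each library. RNA was extracted with miRNeasy Micro and made into cDNA libraries with a low-input NEBNext kit. ATAC-seq, which tags open chromatin with Tn5 transposase, was run on nuclei of sorted cells. Tamoxifen was given to activate MerCreMer, a Cre recombinase. All labels list adult and neonatal doses, so dosing age is unknown for groups taken as adults.

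The RNA values are TPM per gene, a transcript abundance scaled within each library, as deposited by the authors in one table of wild-type (WT) and another of knockout (KO) libraries with identical gene lists of 25746 genes. The submitters' processing notes name STAR 2.5.3a, RSEM, Trim Galore 0.6, FastQC, Bowtie2 2.3, MACS2 and the mouse build mm10, without saying which step each one served. Whether counting used the strand is not given in the sources used here. Near-identical genes (immunoglobulin segments, haemoglobin genes, the Ly6 family, C4a and C4b) may have shared reads, and their values are uncertain. TPM holds no read depth, so the depth of each library is unknown and no counting interval was computed.

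The ATAC-seq values are peak lists, 1 per library, with coordinates on mm10. Per the labels and the deposited peak names, peaks were called for each library on its own. Each peak carries a score, a ratio to background (fold enrichment), a −log10 p and a −log10 q, as deposited by the authors. These values were used only to rank or filter peaks within a list. The lists held 55990 to 93314 peaks over 75.6 to 172.6 Mb, and the weakest peak of a list had a −log10 q between 1.36 and 1.96, so the lists were not made to an equal depth or length. The first letter of the peak names parted the libraries into A and B. The B libraries were KO 3W replicate 2 and WT 3W replicates 2 and 3, and what the letter stands for is not given in the sources used here.

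Groups were taken from the sample titles. The genotype field of the labels matched the title in 16 of 38 samples and differed in 22. Read from the last sample to the first, the field matched all 38 titles, and both gave 11 KO samples. Tcf21 in each library was used as a check of the titles. The groups were WT at postnatal day 12 (P12), WT and KO at 3 weeks of age (3W), WT and KO after 1 or 12 weeks of high-fat diet (HFD) begun at 6 weeks of age, and WT at 6 months (6M) on regular diet. Whether replicates are separate animals is not given, so limma and permutation p-values measure spread between libraries. Titles at 3W name pairs of KO and WT libraries without saying what a pair shares. Of 6 same-pair correlations of deviations from the group means 5 were above 0.1 (lowest -0.13, highest 0.48; pair 3 has 2 WT libraries). The fit stayed without a block as planned, and blocked values are given where they change a call.

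Genes with at least 1 TPM in at least 2 libraries were tested (15659 genes). log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 over all 29 libraries, with a mean for each of 8 groups (21 residual degrees of freedom), no covariate and eBayes with a trend. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A log2 change is on the log2(TPM + 1) scale, which understates changes of low genes. Values after ± are SD for TPM and SE for log2 changes. Exact permutation and sign-flip tests of Tcf21 and Dlk1 were two-sided on the same scale.

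The plan fixed before the data were examined allowed KO against WT only if each column summed to the full nominal total of TPM values; otherwise KO was not to be tested. The columns summed to 918008 to 969385 (KO libraries 938593 to 956206), so this condition was not met as worded. The KO comparisons were made all the same, as a departure from the plan, and repeated after rescaling each column to that total.

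A set of 30 gene lists fixed before the data were examined was tested with camera (preset correlation 0.01), which compares a list with all other genes, adjusted over lists within a comparison. An estimated correlation was the alternative, and fry the self-contained test. The lists were adipogenic transcription factors, lipid storage, inhibitors of adipogenesis, Dpp4-type interstitial progenitors, committed preadipocytes, collagens and structural matrix, matrix enzymes, TGF-beta response, cell cycle, cell cycle inhibitors, chemokines and NF-kB response, interferon response, complement, immediate early genes, imprinted growth genes, the IGF axis, the Wnt, BMP and retinoid pathways, positional transcription factors, hypoxia, cholesterol synthesis, and markers of mesothelium, macrophages, lymphocytes, endothelium, pericytes, erythroid cells, Schwann cells and skeletal muscle. A further list of Y-linked and X-inactivation genes had fewer than 5 tested members and was not tested; its member Ddx3y lay between 26.6 and 148 TPM in every library. In all, 6 list genes were not found in the tables used here.

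Named genes followed a rule set before the data were examined. For each RNA comparison it took Tcf21, a fixed panel, up to 8 higher and 8 lower genes with the largest change among those past the threshold (ranges not overlapping, at least 5 TPM in the higher group, predicted and small RNA genes left out) and the 3 members of each list with the smallest adjusted p. The text names a selection, and some genes that the rule took are not reported here. Cstdc4, Gm42608 and Otop1 fell outside the rule and were named after their values were seen, because counts were 5 or fewer.

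Peaks of all ATAC libraries on the autosomes, X and Y were merged into 123130 regions, and a region was present in a library where at least 1 bp of a peak lay in it. Libraries were compared by the Jaccard index (shared regions over all regions of either) and a PERMANOVA pseudo-F with an exact permutation test over 7560 assignments. A region was gained if present in every library of the first group and in none of the second, and lost in the reverse case. Genes called in RNA-seq were set against gained and lost regions within 50 kb of the gene with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment. Distance was taken from the gene span, not the transcription start as planned, because no table gives the strand. Named regions were the 5 gained and 5 lost with the best mean rank within the lists, of which a selection is given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

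On simulated data with 200 changed genes of 15659 tested, the limma step recovered 85.1% of log2 changes of 2 and 31.3% of changes of 1 for KO against WT at 3W, 62.7% and 14.9% at 1W HFD and 73.1% and 19.4% at 12W HFD, with 10, 6 and 2 false calls. For 12W HFD against 6M it was 59.7% and 17.9%, for 6M against 3W 68.7% and 10.4%, for 3W against P12 73.1% and 20.9%, and in the other WT comparisons at least 82.1% and 28.4% (12W against 1W HFD). A list of unchanged genes passed for KO at 1W HFD (camera adjusted p = 0.0086) and in no other comparison (at least 0.11). The region step recovered all simulated gained and lost regions.

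Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter or at least 5 TPM, a minimum log2 change of 1, median-ratio and quantile scaling, array weights, a fit of the compared groups alone, a replicate block, an estimated correlation, each replicate left out, peaks with −log10 q of at least 5, equal numbers of peaks per library, an overlap of at least 0.5 of the shorter interval, and a distance of 5 kb. Others, named in the closing section, were chosen after seeing the data.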

Results

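Tcf21 is a transcription factor that marks a lineage of progenitor cells in visceral fat. Cells of this lineage were sorted from mouse visceral adipose tissue and profiled by RNA-seq (29 libraries) and ATAC-seq (9 libraries). RNA-seq covered WT cells at postnatal day 12 (P12, n = 2), at 3 weeks (3W, n = 7), after 1 week of high-fat diet (1W HFD, n = 4), after 12 weeks of it (12W HFD, n = 5) and at 6 months on regular diet (6M, n = 2). KO cells were profiled at 3W (n = 5), 1W HFD (n = 2) and 12W HFD (n = 2). ATAC-seq covered KO (n = 2) and WT (n = 3) cells at 3W and WT cells at 1W HFD (n = 2) and 12W HFD (n = 2). Between 10894 and 12825 genes reached 1 TPM in a library, and read depth is unknown. Age, diet and perhaps dosing age differ between HFD groups and 3W or 6M, and between 1W and 12W HFD. Regular-diet cells of HFD ages were not analysed.

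Tcf21 itself (ENSMUSG00000045680, mm10 chromosome 10, 22817281 to 22820174) was lower but still present in the KO libraries. At 3W it averaged 35.2 ± 18.3 TPM in KO cells (n = 5) and 64.9 ± 27.0 TPM in WT cells (n = 7), a log2 change of -0.91 ± 0.35 and a KO level of 54.3% of WT. The two-sided exact permutation test gave p = 0.0341, where the smallest p allowed was 0.00126. The adjusted p of limma was 1. Within the 5 pairs of the titles Tcf21 was lower in KO in 5 of 5 (mean log2 difference -0.89 ± 0.11 SD; exact sign-flip p = 0.0625, the smallest possible). The 5 KO libraries read 20.01, 60.9, 21.9, 48.2 and 25.1 TPM, and the 7 WT libraries 37.6, 109, 46.2, 83.0, 47.6, 83.8 and 47.0 TPM. After 1W HFD the KO libraries read 8.10 and 16.4 TPM and the WT libraries 13.6, 47.4, 11.3 and 19.98 TPM (-0.71 ± 0.52; two-sided exact permutation p = 0.467, smallest possible 0.0667). That change was -0.24 or -1.18 without KO replicate 1 or 2 and -0.30 without WT replicate 2. After 12W HFD the KO libraries read 5.67 and 1.64 TPM and the WT libraries 13.5, 10.2, 5.86, 7.13 and 10.1 TPM (-1.26 ± 0.51; two-sided exact permutation p = 0.0476, which is the smallest possible), and -1.92 or -0.59 without KO replicate 1 or 2. At P12 it read 42.3 and 48.1 TPM, and at 6M 2.24 and 5.54 TPM.

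**Figure D1:**
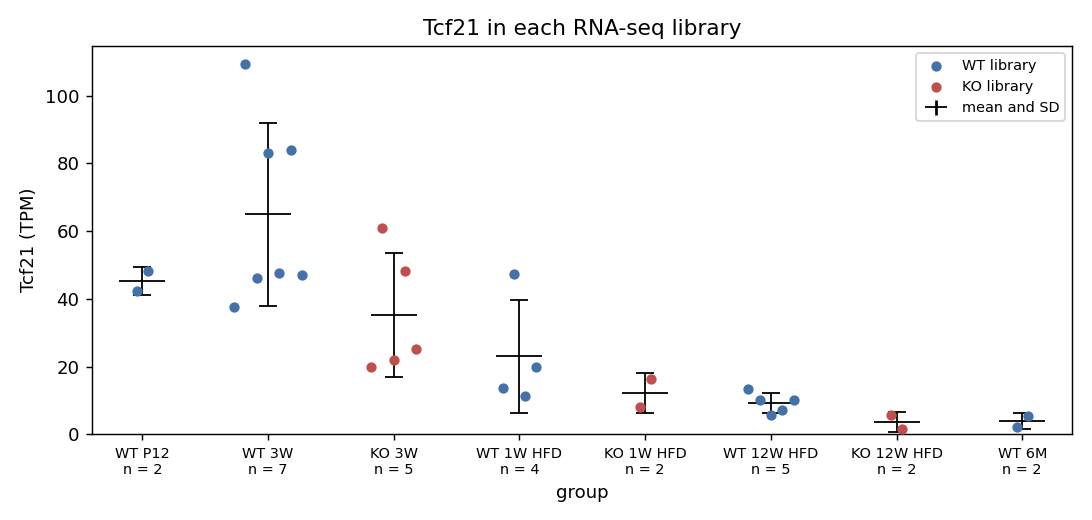
Tcf21 in TPM (vertical axis) for each RNA-seq library, by group (horizontal axis), with WT libraries in blue, KO libraries in red, and a horizontal mark and error bar for the mean and SD. The mean was 64.9 TPM in WT and 35.2 TPM in KO cells at 3W, 9.37 TPM in WT and 3.66 TPM in KO cells after 12W HFD, and 3.89 TPM in WT cells at 6M.

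The first comparison asked what loss of Tcf21 does to lineage cells at 3W. No single gene passed the threshold. The measured differences included lower Dlk1, a preadipocyte protein that holds back adipocyte formation, at 92.9 ± 45.4 TPM in KO (n = 5) and 202 ± 104 TPM in WT (n = 7). Dlk1 differed by -1.11 ± 0.34 (two-sided exact permutation p = 0.0354; limma adjusted p = 1). It was lower in KO in 5 of 5 pairs, at 17.3% to 64.7% of the WT partner over 6 pairings (-1.28 ± 0.53 SD; exact sign-flip p = 0.0625, the smallest possible). Its list partners Igf2, a fetal growth factor (66.8 against 112 TPM, -0.64 ± 0.43), and Zim1 (-0.59 ± 0.31) were on the same side of 0 and did not pass (adjusted p = 1). The imprinted growth genes lay lower than other genes as a list (camera adjusted p = 0.0185, or 0.36 with an estimated correlation), with 0 of 16 members passing over all genes and 1 lower when adjusted over the list alone. Imprinted genes lost the call without 1 library (adjusted p = 0.325 without KO replicate 1 and 0.0526 without WT replicate 3).

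At 3W, of 41 collagen and structural matrix genes 37 had a positive change (camera adjusted p = 1.88e-07, or 0.601 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. Examples were Col1a1, the main fibrillar collagen (0.70 ± 0.44), Postn, a matrix protein of activated fibroblasts (0.71 ± 0.36), and Fmod, a collagen-binding proteoglycan (207 against 108 TPM, 0.97 ± 0.41), each with adjusted p = 1. Matrix enzymes were also higher (26 of 33 positive; adjusted p = 0.000273, and 0.601 with an estimated correlation), among them the protease Mmp3 (172 against 52.9 TPM, 1.26 ± 0.53). Of 17 markers of Dpp4-type interstitial progenitors 15 were positive (adjusted p = 0.00479, or 0.601 with an estimated correlation). Matrix enzymes lost the call without 1 library (adjusted p = 0.167 without WT replicate 2), as did Dpp4-type markers (0.413 without KO replicate 1 and 0.267 and 0.0654 without WT replicates 2 and 3).

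Of 32 cell cycle genes 29 were positive in KO cells at 3W (adjusted p = 0.000273, or 0.779 with an estimated correlation), such as the proliferation marker Mki67 (4.69 ± 4.33 against 1.79 ± 1.74 TPM, 0.97 ± 0.42). KO replicate 1 stood apart, with cell cycle genes at 5.17 log2 units against 2.37 to 3.91 in the other KO and 2.31 to 4.29 in the WT libraries. Lipid storage genes were at adjusted p = 0.0496 (0.779 with an estimated correlation), with the fatty acid binding protein Fabp4 at 0.60 ± 0.44 and the adipokine Adipoq at 0.90 ± 0.82. Immediate early genes were lower (22 of 26 negative; adjusted p = 0.0193, and 0.786 with an estimated correlation). They averaged 6.35 log2 units in KO replicate 1, 8.13 to 8.42 in the other KO and 7.51 to 8.83 in the WT libraries. Cell cycle genes lost the call without 1 library (adjusted p = 0.989 without KO replicate 1), as did lipid storage (0.866, 0.3 and 0.236 without KO replicates 1, 3 and 5 and 0.105, 0.602 and 0.0947 without WT replicates 1, 3 and 6). Immediate early genes lost it (0.075 in the other direction without KO replicate 1 and 0.376, 0.0551 and 0.0512 without WT replicates 3, 4 and 6). With the pair numbers of the titles as a block, the adjusted p was 0.0979 for cell cycle genes and for lipid storage and 0.274 for immediate early genes. Chemokines (0.00117) and interferon response genes (0.00265) then passed, both higher, at adjusted p = 0.505 and 0.588 with an estimated correlation. None of the Dpp4-type, matrix enzyme, cell cycle, lipid storage or immediate early genes passed over all genes or adjusted over the list alone. Of the lists that did not pass, cell cycle inhibitors were at adjusted p = 0.0501, and the median (0.02) and mean (-0.04) of hypoxia genes (0.821) differed in sign.

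Markers of other cell types moved beside these lists. Macrophage markers averaged 2.90 ± 0.60 log2 units in KO (n = 5) and 2.03 ± 0.54 in WT libraries (n = 7), with 18 of 20 positive, 0 passing over all genes and 5 higher when adjusted over the list alone (camera adjusted p = 1.22e-11, or 0.156 with an estimated correlation). The lysosomal protease Ctss was at 7.82 against 2.33 TPM (1.68 ± 0.42, adjusted p = 0.963), and the antigen presentation genes Cd74 (159 against 40.6 TPM) and H2-Aa were at 2.15 ± 0.60 and 2.10 ± 0.65. Endothelial markers were higher (13 of 17 positive; adjusted p = 0.00245, and 0.601 with an estimated correlation), with the junction protein Cldn5 at 1.74 ± 0.75. With limma, 0 genes passed and 546 had an unadjusted p under 0.05, where 783 would be expected by chance; without WT 3W replicate 1, 2 genes passed, both lower in KO. The plan allowed these KO tests only for columns of equal sum, which the deposited columns do not have; after rescaling the columns, 0 genes passed and Tcf21 was at -0.91. Endothelial markers lost the call without 1 library (adjusted p = 0.14 without KO replicate 3).

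After 1W HFD, 4 genes were higher in KO cells and 0 lower. Ighv2-6-8, an immunoglobulin heavy chain segment, read 19.3 and 21.5 TPM in the KO libraries and was listed at 0 in all 4 WT libraries (limma adjusted p = 0.00023). Lrrn4, a mesothelial marker, read 8.35 and 2.86 TPM against 4 WT libraries listed at 0 (adjusted p = 0.00023). Cstdc4 read 1.33 and 1.06 TPM, again with all 4 WT libraries listed at 0 (adjusted p = 0.0195), and the predicted gene Gm42608 read 3.78 and 1.35 TPM against 0, 0.03, 0 and 0 (adjusted p = 0.0454). The last 2 were named after their values were seen. Read depth is unknown, so a listed 0 does not show absence. An unadjusted p under 0.05 was reached by 540 genes.

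Several lists separated at 1W HFD. Mesothelial markers were higher, with Upk3b at 17.2 ± 19.9 against 1.19 ± 0.843 TPM (2.48 ± 0.80); 1 of 14 members passed over all genes and 6 when adjusted over the list alone (camera adjusted p = 1.12e-07, or 0.0862 with an estimated correlation). Of 32 cell cycle genes 31 were positive (adjusted p = 1e-12, or 0.354 with an estimated correlation), with the mitotic enzyme gene Ube2c at 2.05 ± 0.87. The cell cycle genes averaged 3.2 and 4.96 log2 units in the KO libraries and 2.07 to 3.62 in the WT libraries. Chemokines and cytokines were higher (adjusted p = 0.000828, or 0.428 with an estimated correlation), with the acute phase gene Saa3 at 5.12 ± 1.69. Inhibitors of adipogenesis were lower (adjusted p = 0.00262, or 0.0862 with an estimated correlation), with Dlk1 at 0.11 and 0.78 TPM in KO against 4.03, 4.32, 1.98 and 3.41 TPM in WT. Imprinted genes (adjusted p = 0.0348, or 0.354 with an estimated correlation), including Igf2 (-2.22 ± 0.64, adjusted p = 0.902), and BMP pathway genes (adjusted p = 0.019, or 0.354 with an estimated correlation) were lower. Over all genes 0 members of these last 5 lists passed; adjusted over the list alone, 1 inhibitor of adipogenesis and 2 imprinted genes were lower. The call was lost without KO replicate 1 for mesothelial markers (adjusted p = 0.221), imprinted (0.0932) and BMP genes (0.13), and without KO replicate 2 for cell cycle genes (0.703), chemokines (0.916, in the other direction), inhibitors of adipogenesis (0.0589), imprinted (0.147) and BMP genes (0.0589). Imprinted genes lost it too without WT replicates 2 and 4 (0.115 and 0.0693) and BMP genes without WT replicates 1 and 2 (0.125 and 0.0574).

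Macrophage markers stood beside these lists at 4.82 ± 0.25 log2 units in KO (n = 2) and 4.15 ± 0.21 in WT libraries (n = 4), 19 of 20 positive (adjusted p = 8.33e-05, or 0.354 with an estimated correlation). Erythroid markers were higher (adjusted p = 0.00367, or 0.428 with an estimated correlation). The count of 4 genes became 9 or 28 without KO replicate 1 or 2, and 2 without WT replicate 1, 3 or 4. Leaving out 1 of 2 libraries, here and for KO 12W HFD, P12 and 6M, leaves a lone library that is assumed to vary like the other groups, from which limma takes the spread. On simulated data a list of unchanged genes passed in this comparison (camera adjusted p = 0.0086). After rescaling the columns, whose sums did not meet the planned condition, 3 genes passed and Tcf21 was at -0.72. Macrophage markers lost the call without 1 library (adjusted p = 0.0589 without KO replicate 2), as did erythroid markers (0.0593 without KO replicate 1 and 0.115 without WT replicate 2).

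After 12W HFD, 1 gene was higher in KO cells and 0 lower: Otop1, a proton channel, read 2.16 and 1.11 TPM in KO against 0.46, 0, 0, 0 and 0 in WT libraries (1.26 ± 0.21; limma adjusted p = 0.0341; named after its values were seen; depth unknown). Of 30 chemokine, cytokine and NF-kB genes 28 were positive, with 0 passing over all genes and 4 when adjusted over the list alone (camera adjusted p = 1.69e-13, or 0.113 with an estimated correlation). The alarmin Il33 was at 648 ± 75.0 against 193 ± 105 TPM (1.86 ± 0.50, adjusted p = 0.61) and Cxcl5 at 2.55 ± 0.79. Dlk1 was listed at 0 in both KO libraries and at 0.9, 0, 0.78, 0.88 and 1.07 TPM in WT (two-sided exact permutation p = 0.143, smallest possible 0.0476). Igf2 was at 1.46 ± 0.62.

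Other lists past the threshold with the preset correlation were matrix enzymes, higher (adjusted p = 8.54e-06, or 0.416 with an estimated correlation) with Mmp3 at 1355 against 407 TPM (1.86 ± 0.75), and collagens, higher (adjusted p = 0.0041, or 0.749 with an estimated correlation). Committed preadipocyte markers (adjusted p = 0.000889, or 0.317 with an estimated correlation), complement (adjusted p = 0.0197, or 0.428 with an estimated correlation) and immediate early genes (adjusted p = 8.54e-06, or 0.428 with an estimated correlation) were higher. Dpp4-type progenitor markers were lower (adjusted p = 0.00971, or 0.656 with an estimated correlation), with Sema3c, a secreted guidance cue, at 15.5 against 46.4 TPM (-1.43 ± 0.38, adjusted p = 0.54) and Dpp4 at -1.23 ± 0.55. Interferon response genes were lower (adjusted p = 0.000186, or 0.656 with an estimated correlation). Of these lists 0 members passed over all genes, and 1 Dpp4-type marker was lower when adjusted over the list alone. Median, mean and test differed in sign for the lipid storage, inhibitor of adipogenesis, Wnt, retinoid, positional and Schwann cell lists. The call was lost without KO replicate 1 for complement (adjusted p = 0.239) and immediate early genes (0.417), without KO replicate 2 for Dpp4-type markers (0.251), and without WT replicates 1 and 2 for interferon response (0.69) and collagens (0.0504) in turn.

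Beside these lists, macrophage markers averaged 6.11 ± 0.36 log2 units in KO (n = 2) and 6.85 ± 0.44 in WT libraries (n = 5) (adjusted p = 8.54e-06, or 0.366 with an estimated correlation), with Cd74 at 930 ± 363 against 3875 ± 2990 TPM. Lymphocyte markers were lower (adjusted p = 9.26e-06, or 0.317 with an estimated correlation), with the T cell receptor component Cd3d at -1.40 ± 0.33 (adjusted p = 0.368). Endothelial markers were higher (adjusted p = 0.0197, or 0.749 with an estimated correlation). An unadjusted p under 0.05 was reached by 570 genes. The count of 1 became 2 or 14 without KO replicate 1 or 2, and 10, 0, 0, 4 and 4 without WT replicates 1 to 5; it was 5 higher and 1 lower with median-ratio scaling, 4 and 1 with quantile scaling, and 1 after rescaling the columns (Tcf21 at -1.26), the planned condition on column sums not being met. Endothelial markers lost the call without 1 library (adjusted p = 0.0754 and 0.0864 without KO replicates 1 and 2 and 0.166 and 0.173 without WT replicates 2 and 5).

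The next comparisons followed WT cells over age and diet. Between P12 and 3W, 98 genes rose and 157 fell. The split was 126 and 84 with a pseudocount of 0.1, 3 and 56 in a fit of the compared groups alone and 11 and 32 with array weights. Pecam1, an adhesion protein of vessel walls, went from 71.1 ± 48.1 TPM (n = 2) to 1.53 ± 1.18 TPM (n = 7), a log2 change of -4.81 ± 0.81 (limma adjusted p = 0.00108). Vwf, the clotting factor carrier (-4.95 ± 0.83) and Cldn5 (-4.91) fell as well. Of 17 endothelial markers 10 fell over all genes and 15 adjusted over the list alone (camera adjusted p = 4.29e-18, or 0.0529 with an estimated correlation). Erythroid markers rose, 4 of 7 over all genes and 5 adjusted over the list alone (adjusted p = 1.49e-07, or 0.122 with an estimated correlation), with the haemoglobin gene Hba-a1 at 1552 ± 1008 against 118 ± 162 TPM (5.34 ± 1.21).

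Between P12 and 3W the growth factor binding protein Igfbp6 rose from 622 ± 282 to 3041 ± 986 TPM (2.29 ± 0.32; adjusted p = 0.000193), and the transcription factor Msc (2.81 ± 0.49) and Pdgfra (0.97 ± 0.25) rose. Complement genes were higher as a list, with 2 of 14 passing over all genes (C1qtnf7 at 1.55 and the complement inhibitor Serping1 at 1.22) and 5 adjusted over the list alone (adjusted p = 2.7e-05, or 0.122 with an estimated correlation). Of 18 adipogenic transcription factors the sterol receptor Nr1h3 rose (1.66), 3 with adjustment over the list alone (adjusted p = 0.00123, or 0.122 with an estimated correlation). The replication genes Mcm3 (11.1 against 46.2 TPM, -2.07) and Mcm4 (-1.32; adjusted p = 0.0441, and 0.0531 with median-ratio scaling) fell, 2 of 32 cell cycle genes (adjusted p = 7.81e-05, or 0.633 with an estimated correlation). Igf2 was at -1.98 ± 0.59 (adjusted p = 0.0858) and Tcf21 at 0.42 ± 0.49 (adjusted p = 0.759). Cell cycle genes lost the call without 1 library (adjusted p = 0.0889 without P12 replicate 2).

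Lists with few or no single calls in this comparison were Dpp4-type markers, higher (adjusted p = 0.00111, or 0.6 with an estimated correlation), interferon response, higher (adjusted p = 0.00111, or 0.633 with an estimated correlation), matrix enzymes, higher (adjusted p = 0.0194, or 0.647 with an estimated correlation), and the Wnt pathway, higher (adjusted p = 0.0241, or 0.46 with an estimated correlation). TGF-beta response genes (adjusted p = 0.0295, or 0.633 with an estimated correlation), pericyte markers (adjusted p = 0.000944, or 0.532 with an estimated correlation) and macrophage markers (adjusted p = 0.0115, or 0.633 with an estimated correlation) were lower; 0 of 20 macrophage markers passed over all genes and 3 adjusted over the list alone. Mesothelial markers were at adjusted p = 0.0988. Median, mean and test differed in sign for inhibitors of adipogenesis, committed preadipocyte markers, collagens, cell cycle inhibitors, the IGF axis, positional factors and Schwann cell markers. The count of 255 genes became 420 without P12 replicate 2. Without P12 replicate 2 the call was lost for Dpp4-type markers (adjusted p = 0.699), matrix enzymes (0.951), Wnt genes (0.675) and macrophage markers (0.349), and 7 lists passed in place of 12. Without P12 replicate 1 it was lost for TGF-beta response (0.52) and pericyte markers (0.0869). Matrix enzymes lost it too without 3W replicates 1 and 6 (0.065 and 0.0646) and TGF-beta response without 3W replicates 1 and 7 (0.135 and 0.0536).

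Between 3W and 6M, 626 genes rose and 1073 fell. The median of all genes moved by -0.24, and log2 changes here are given relative to it; the split was 943 higher and 586 lower with median-ratio scaling and 763 and 594 with quantile scaling, and 345 and 341 in a fit of the compared groups alone. Macrophage markers went from 2.03 ± 0.54 (n = 7) to 6.04 ± 0.77 log2 units (n = 2), and 18 of 20 rose over all genes and 20 adjusted over the list alone (camera adjusted p = 2.72e-38, or 0.000362 with an estimated correlation). The lysozyme gene Lyz2 went from 16.2 ± 8.17 to 1085 ± 771 TPM (6.21; adjusted p = 3.76e-07), Ctss from 2.33 to 168 TPM (6.21) and the immune adaptor Tyrobp rose by 5.27. Of 13 lymphocyte markers 7 rose, 10 adjusted over the list alone (adjusted p = 1.29e-10, or 0.0265 with an estimated correlation).

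Tcf21 fell from 64.9 ± 27.0 to 3.89 ± 2.33 TPM (-3.50; adjusted p = 9.28e-06). Dlk1 fell from 202 ± 104 to 0.63 ± 0.141 TPM (-6.55; adjusted p = 2.32e-10), Igf2 fell by 5.46 and the imprinted transcription factor Peg3 fell by 4.08. Of 16 imprinted growth genes 8 fell (adjusted p = 3.61e-08, or 0.000833 with an estimated correlation), of 17 IGF axis genes 5 (adjusted p = 0.00106, or 0.0219 with an estimated correlation), with the carrier protein Igfbp3 at 22.6 against 1141 TPM (-5.33), and of 14 cell cycle inhibitors 7 (adjusted p = 0.000155, or 0.0432 with an estimated correlation). Adjusted over the list alone these counts were 8, 6 and 9.

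Of 21 TGF-beta response genes 9 fell at 6M (adjusted p = 0.000252, or 0.213 with an estimated correlation), with Acta2 at -4.07 and the calponin Cnn1 at -5.20. Of 41 matrix genes 13 fell and 1 rose (adjusted p = 0.00252, or 0.53 with an estimated correlation), with Col1a1 at 290 ± 107 against 2644 ± 1779 TPM (-2.75) and Col3a1 at -1.14 (adjusted p = 0.0289, and 0.0942 with median-ratio scaling). Of 17 Dpp4-type progenitor markers 7 rose (adjusted p = 3.91e-06, or 0.177 with an estimated correlation), with Ly6a at 2.32. Chemokines were higher (7 rose and 1 fell of 30; adjusted p = 8.64e-05, or 0.213 with an estimated correlation), with Ccl8 at 843 against 5.93 TPM (6.86) and Ccl2 at 3.03. Complement was higher (4 rose and 1 fell of 14; adjusted p = 0.00545, or 0.213 with an estimated correlation), with C3 at 2.75. Adjusted over the list alone, 11 TGF-beta response genes and 17 matrix genes were lower, and 7 Dpp4-type markers, 9 chemokines and 5 complement genes were higher. In the same libraries macrophage markers averaged 6.04 and lymphocyte markers 2.86 ± 1.48 log2 units, against 2.03 and 0.66 ± 0.21 at 3W. Chemokines lost the call without 1 library (adjusted p = 0.136 without 6M replicate 1), as did complement (0.238 without 6M replicate 1).

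At 6M, of 28 Wnt genes 8 fell and 1 rose (adjusted p = 0.037, or 0.255 with an estimated correlation), with the Wnt amplifier Rspo3 at -3.80. Of 24 BMP genes 7 fell and 1 rose (adjusted p = 0.00698, or 0.213 with an estimated correlation). Inhibitors of adipogenesis (7 fell, 1 rose; adjusted p = 0.0122, or 0.116 with an estimated correlation), positional transcription factors (6 of 22 fell; adjusted p = 0.00545, or 0.116 with an estimated correlation) and pericyte markers (4 of 13 fell; adjusted p = 0.0069, or 0.405 with an estimated correlation) were lower. Lower members adjusted over the list alone were 8 Wnt genes, 8 BMP genes, 8 inhibitors of adipogenesis, 8 positional factors and 5 pericyte markers. Interferon response (3 of 26 rose; adjusted p = 0.000201, or 0.436 with an estimated correlation), erythroid markers (1 of 7; adjusted p = 0.00134, or 0.255 with an estimated correlation) and cholesterol synthesis (0 of 20; adjusted p = 0.0166, or 0.565 with an estimated correlation) were higher. For the retinoid and endothelial lists the test pointed up while median and mean were below 0 (adjusted p = 0.958 for both). The count of 1699 genes became 778 without 6M replicate 1 and 886 without replicate 2, where the split was 525 higher and 361 lower. Wnt genes lost the call without 1 library (adjusted p = 0.0616 and 0.0521 without 3W replicates 1 and 6 and 0.325 without 6M replicate 2), as did pericyte markers (0.0919 without 6M replicate 1). Interferon response lost it (0.17 without 6M replicate 1), as did cholesterol synthesis (0.0557 and 0.0556 without 3W replicates 2 and 5 and 0.917 in the other direction without 6M replicate 2).

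After 1W HFD, 748 genes were higher than at 3W and 509 lower. Dpp4, the surface peptidase that names the interstitial progenitors, rose from 17.0 ± 17.5 (n = 7) to 77.8 ± 17.7 TPM (n = 4), a log2 change of 2.49 ± 0.41 (limma adjusted p = 0.000433). Cd55 (1.96 ± 0.26), Ly6a (2.11 ± 0.42) and Bmp7 (1.94) rose as well, 10 of 17 members over all genes and 14 adjusted over the list alone (camera adjusted p = 3.71e-11, or 0.0584 with an estimated correlation). Dlk1 fell from 202 ± 104 to 3.44 ± 1.04 TPM (-5.38 ± 0.36; adjusted p = 1.67e-10), Igf2 from 112 to 7.79 TPM (-3.42 ± 0.46) and Zim1 fell by 2.79. Of 16 imprinted growth genes 6 fell, 8 adjusted over the list alone (adjusted p = 1.03e-08, or 0.00122 with an estimated correlation). Tcf21 fell from 64.9 to 23.1 TPM (-1.57 ± 0.38; adjusted p = 0.00936). The count of 1257 genes became 665 without 1W HFD replicate 3 and 700 without replicate 4, and 730 in a fit of the compared groups alone.

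In the same libraries macrophage markers went from 2.03 ± 0.54 to 4.15 ± 0.21 log2 units, and 16 of 20 rose, both over all genes and adjusted over the list alone (adjusted p = 2.04e-17, or 0.015 with an estimated correlation), with Lyz2 at 115 against 16.2 TPM (2.93), Cd74 at 420 against 40.6 TPM (3.94) and Ctss at 2.78. Endothelial markers went from 1.66 ± 0.25 to 3.43 ± 0.67 log2 units, and 10 of 17 rose, 13 adjusted over the list alone (adjusted p = 1.85e-09, or 0.119 with an estimated correlation), with Pecam1 at 27.8 ± 22.9 against 1.53 ± 1.18 TPM (3.38) and Cldn5 at 4.79 ± 0.80. Of 13 lymphocyte markers 0 passed with limma over all genes or the list alone, where 3391 of all genes had an unadjusted p under 0.05.

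Of 26 interferon response genes 8 rose after 1W HFD (10 adjusted over the list alone; adjusted p = 2.32e-08, or 0.331 with an estimated correlation). Chemokines were higher (4 rose and 1 fell of 30, 9 and 1 adjusted over the list alone; adjusted p = 0.00782, or 0.41 with an estimated correlation) with Ccl2 at 1.79 (adjusted p = 0.0487, and 0.067 with median-ratio scaling). Complement was higher (4 of 14; adjusted p = 0.0334, or 0.353 with an estimated correlation), and matrix enzymes were higher (4 of 33; adjusted p = 0.017, or 0.555 with an estimated correlation). Cholesterol synthesis was higher with 0 of 20 passing (adjusted p = 0.00352, or 0.444 with an estimated correlation). Lower lists were the IGF axis (3 of 17; adjusted p = 0.00661, or 0.0584 with an estimated correlation) with Igfbp3 at -4.96. So were TGF-beta response (6 fell, 1 rose; adjusted p = 0.00764, or 0.353 with an estimated correlation) with Acta2 at -2.81, and cell cycle inhibitors (2 of 14; adjusted p = 0.014, or 0.241 with an estimated correlation). Wnt genes (6 of 28; adjusted p = 0.0288, or 0.326 with an estimated correlation) with Rspo3 at -2.02, retinoid genes (4 of 17; adjusted p = 0.0371, or 0.221 with an estimated correlation), and immediate early genes (1 of 26; adjusted p = 0.0361, or 0.665 with an estimated correlation) were lower. Adjusted over the list alone, 5 complement genes and 4 matrix enzymes were higher, and 3 IGF axis genes, 7 TGF-beta response genes, 3 cell cycle inhibitors, 7 Wnt genes and 5 retinoid genes lower. Median, mean and test differed in sign for inhibitors of adipogenesis, mesothelial and pericyte markers. In the same libraries macrophage markers averaged 4.15 and endothelial markers 3.43 log2 units. Complement lost the call without 1 library (adjusted p = 0.0504 and 0.1 without 3W replicates 2 and 7 and 0.138 and 0.0513 without 1W HFD replicates 1 and 4), as did matrix enzymes (0.176 without 3W replicate 2 and 0.0519 without 1W HFD replicate 2). Wnt genes lost it (0.0647 and 0.0513 without 1W HFD replicates 3 and 4), as did retinoid genes (0.0791, 0.0699 and 0.0559 without 3W replicates 3, 4 and 5 and 0.0641, 0.0546 and 0.0652 without 1W HFD replicates 2, 3 and 4). Immediate early genes lost it (0.144 and 0.0686 without 3W replicates 3 and 4 and 0.0588 and 0.16 without 1W HFD replicates 1 and 3).

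After 12W HFD, 1244 genes were higher than at 3W and 976 lower. Macrophage markers went from 2.03 ± 0.54 (n = 7) to 6.85 ± 0.44 log2 units (n = 5); 18 of 20 rose, 19 adjusted over the list alone (camera adjusted p = 8.23e-40, or 0.00014 with an estimated correlation). The lysosomal glycoprotein Cd68 went from 8.93 ± 5.13 to 540 ± 226 TPM (5.85 ± 0.33), Ctss from 2.33 to 724 TPM (7.93 ± 0.42; limma adjusted p = 1.31e-13), Tyrobp rose by 6.41 and the macrophage elastase Mmp12 went from 0.0929 to 445 TPM (7.93). Of 13 lymphocyte markers 12 rose, 12 also adjusted over the list alone (adjusted p = 2.58e-10, or 0.0247 with an estimated correlation), and the immunoglobulin gene Igkc rose (9.91).

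**Figure D2:**
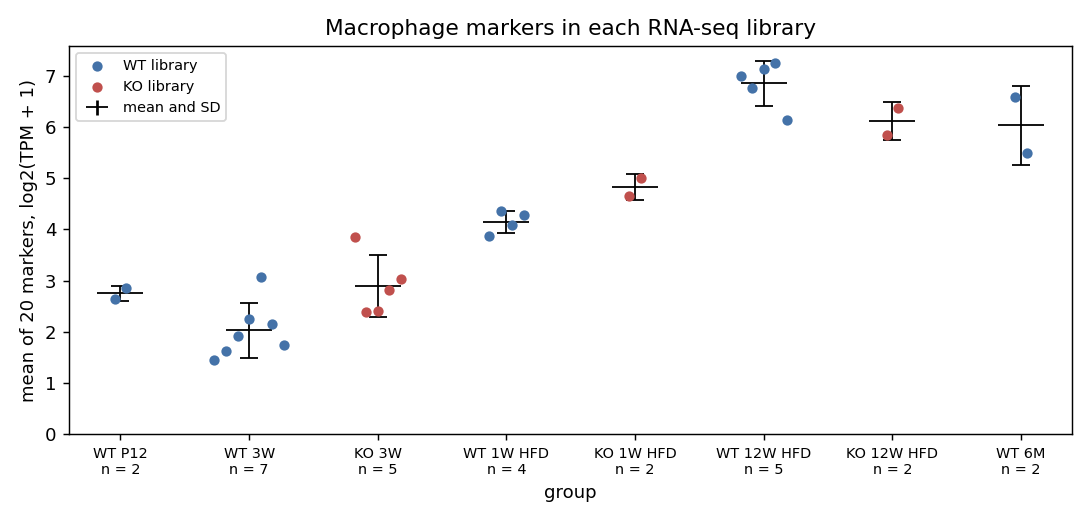
Mean of 20 macrophage markers as log2(TPM + 1) (vertical axis) for each RNA-seq library, by group (horizontal axis), with WT libraries in blue, KO libraries in red, and a horizontal mark and error bar for the mean and SD. The mean was 2.03 in WT cells at 3W, 4.15 after 1W HFD, 6.85 after 12W HFD and 6.04 at 6M.

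Tcf21 fell from 64.9 ± 27.0 to 9.37 ± 2.98 TPM (-2.62 ± 0.35; adjusted p = 2.91e-06) after 12W HFD. Dlk1 fell from 202 ± 104 to 0.726 ± 0.419 TPM (-6.75 ± 0.34), Igf2 from 112 to 0.24 TPM (-6.28 ± 0.43) and Igfbp3 fell by 4.37. Of 16 imprinted genes 9 fell (adjusted p = 5.02e-11, or 0.00014 with an estimated correlation). Counts of falling members were 5 of 17 IGF axis genes (adjusted p = 0.000672, or 0.0145 with an estimated correlation), 8 of 28 Wnt genes (adjusted p = 8.8e-05, or 0.0259 with an estimated correlation) with Rspo3 at -4.22. They were 9 of 24 BMP genes (adjusted p = 1.6e-05, or 0.0247 with an estimated correlation) with Bambi at -2.51, and 5 of 14 inhibitors of adipogenesis (adjusted p = 0.00079, or 0.0247 with an estimated correlation). Adjusted over the list alone these counts were 9, 7, 10, 12 and 6.

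Adipocyte and matrix genes went both ways after 12W HFD. Of 32 lipid storage genes 10 fell and 4 rose (14 and 5 adjusted over the list alone; camera adjusted p = 0.0935), with Adipoq at 4.86 ± 4.73 against 51.8 ± 51.5 TPM (-2.54 ± 0.82; adjusted p = 0.0349), the fatty acid transporter Cd36 at 596 ± 295 against 79.3 ± 42.7 TPM (3.01 ± 0.50). Of 18 adipogenic transcription factors 6 fell (adjusted p = 0.00733, or 0.143 with an estimated correlation). Of 41 matrix genes 13 fell and 5 rose (adjusted p = 0.0285, or 0.559 with an estimated correlation); Col1a1 fell from 2644 to 665 TPM (-1.96 ± 0.44), and Col3a1 (-1.16) and Mfap4 (-2.98) fell, while Col8a1 rose (4.40). The protease inhibitor Timp1 rose from 63.7 to 695 TPM (3.53). With p adjusted over the list alone, 6 adipogenic factors and 14 matrix genes were lower. Macrophage markers averaged 6.85 log2 units in the same libraries. Collagens lost the call without 1 library (adjusted p = 0.0785, 0.0706, 0.0881 and 0.0559 without 3W replicates 1, 5, 6 and 7 and 0.104 and 0.0684 without 12W HFD replicates 2 and 3).

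Other lists past the threshold were chemokines, higher (9 rose, 1 fell; adjusted p = 0.000822, or 0.373 with an estimated correlation). Interferon response was higher (6 of 26, 13 adjusted over the list alone; adjusted p = 2.38e-06, or 0.373 with an estimated correlation), as were cholesterol synthesis (4 of 20; adjusted p = 0.0126, or 0.53 with an estimated correlation), and endothelial markers (5 of 17; adjusted p = 0.0191, or 0.522 with an estimated correlation). Lower were TGF-beta response (9 fell, 1 rose; adjusted p = 0.0352, or 0.522 with an estimated correlation). So were cell cycle inhibitors (3 fell, 1 rose; adjusted p = 0.0244, or 0.263 with an estimated correlation), immediate early genes (4 fell, 1 rose; adjusted p = 0.0164, or 0.559 with an estimated correlation), positional factors (4 fell, 1 rose; adjusted p = 0.0164, or 0.143 with an estimated correlation) and pericyte markers (3 of 13; adjusted p = 0.0279, or 0.522 with an estimated correlation). Rbp4 fell by 4.48 and the complement genes C4b (3.88) and C3 (1.92) rose, with complement as a list at adjusted p = 0.0718. Adjusted over the list alone, 10 chemokines, 4 cholesterol genes and 5 endothelial markers were higher, and 9 TGF-beta response genes, 3 cell cycle inhibitors, 5 immediate early genes, 5 positional factors and 3 pericyte markers lower. Hypoxia genes (adjusted p = 0.88), Schwann cell markers (0.633), skeletal muscle markers (0.172) and mesothelial markers (0.172) did not pass. Median, mean and test differed in sign for the cell cycle, hypoxia and Schwann cell lists. Endothelial markers lost the call without 1 library (adjusted p = 0.183 without 12W HFD replicate 4), as did TGF-beta response (0.0673, 0.0724 and 0.0559 without 3W replicates 2, 3 and 6 and 0.0511 without 12W HFD replicate 4). Immediate early genes lost it (0.0556 without 3W replicate 3 and 0.0561 without 12W HFD replicate 2), as did pericyte markers (0.0735 and 0.0614 without 3W replicates 2 and 6 and 0.0535 without 12W HFD replicate 2).

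Between 1W and 12W HFD, 554 genes rose and 374 fell (644 and 267 with median-ratio scaling, 915 and 967 with array weights). Cd68 went from 28.9 ± 4.92 (n = 4) to 540 ± 226 TPM (n = 5), a log2 change of 4.07 ± 0.38 (limma adjusted p = 4.15e-08), and the lipid receptor Trem2 from 0.915 to 163 TPM (6.26 ± 0.57). Spp1 (6.18) and Mmp12 (7.68) rose. Of 20 macrophage markers 16 rose, 18 adjusted over the list alone (camera adjusted p = 6.64e-27, or 0.00319 with an estimated correlation), and of 13 lymphocyte markers 7, 11 adjusted over the list alone (adjusted p = 1.48e-11, or 0.0375 with an estimated correlation).

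Of 17 Dpp4-type progenitor markers 8 fell, 11 adjusted over the list alone (adjusted p = 1.54e-07, or 0.163 with an estimated correlation). The sialomucin Cd34 fell from 1571 ± 116 to 622 ± 107 TPM (-1.35 ± 0.18; adjusted p = 7.55e-06), and Cd55 (-1.19) and Bmp7 (-2.63) fell. Of 41 matrix genes 9 fell, 13 adjusted over the list alone (adjusted p = 5.93e-05, or 0.42 with an estimated correlation), with the collagen-binding protein Sparc at 4602 ± 1612 against 11920 ± 2140 TPM (-1.43). Imprinted genes (4 of 16; adjusted p = 0.00746, or 0.116 with an estimated correlation), with Igf2 at -2.86, were lower. Wnt genes (4 of 28; adjusted p = 0.0122, or 0.231 with an estimated correlation), with Rspo3 at -2.20, BMP genes (5 of 24; adjusted p = 0.00427, or 0.184 with an estimated correlation), inhibitors of adipogenesis (4 of 14; adjusted p = 0.00792, or 0.116 with an estimated correlation) and endothelial markers (1 of 17; adjusted p = 0.00122, or 0.392 with an estimated correlation) were lower. Erythroid markers were higher (1 of 7; adjusted p = 0.00554, or 0.392 with an estimated correlation). Counts adjusted over the list alone were 4 imprinted, 4 Wnt and 6 BMP genes, 5 inhibitors of adipogenesis and 3 endothelial markers, all lower. Median, mean and test differed in sign for the cell cycle inhibitor, retinoid, hypoxia, Schwann cell and skeletal muscle lists. Tcf21 was at -1.04 ± 0.41 (adjusted p = 0.143). Wnt genes lost the call without 1 library (adjusted p = 0.0755 without 1W HFD replicate 2), as did erythroid markers (0.0728 without 1W HFD replicate 2 and 0.0598 without 12W HFD replicate 2).

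Between 6M (older, regular diet) and 12W HFD, 110 genes were higher after HFD and 28 lower. In a fit of the compared groups alone 0 genes passed (limma, 2673 with unadjusted p under 0.05). The median of all genes moved by 0.22, and log2 changes are relative to it; the split was 62 and 41 with median-ratio scaling and 47 and 38 with quantile scaling. Atp6v0d2, a subunit of the lysosomal proton pump, was at 55.4 ± 31.9 TPM (n = 5) against 2.04 ± 2.36 TPM (n = 2), a relative change of 4.04 (limma adjusted p = 1.2e-05). Trem2 (163 against 15.2 TPM, 3.28) and Cd36 (2.94) were higher. Cd68 (1.88; adjusted p = 0.0273), the collagen crosslinker Lox (1.30; 0.0308) and Id2 (1.82; 0.0212) passed but not with median-ratio scaling (adjusted p = 0.0655, 0.0833 and 0.0543). Ighv11-1 was listed at 0 in all 5 libraries after HFD and at 2687 and 0.97 TPM at 6M (adjusted p = 0.0159), and the neutrophil gene S100a9 (-3.54) was lower. Tcf21 was at 0.91 (adjusted p = 0.314).

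Of 30 lists 8 passed between these groups with the preset correlation and 0 with an estimated one, where each had adjusted p = 0.712. Dpp4-type markers were lower (adjusted p = 9.3e-07; 0 of 17 over all genes and 2 adjusted over the list alone) and stayed past the threshold without any 1 library. Markers of other cell types moved beside them. Macrophage markers averaged 6.85 ± 0.44 log2 units after HFD and 6.04 ± 0.77 at 6M, higher (adjusted p = 0.0469; 1 of 20 over all genes and 5 adjusted over the list alone), endothelial markers 2.45 ± 0.83 and 1.39 ± 0.01, higher (adjusted p = 0.0249; 0 of 17 and 2), and erythroid markers 6.93 ± 1.32 and 7.87 ± 0.88, lower (adjusted p = 0.0249; 0 of 7 and 0). Committed preadipocyte markers (adjusted p = 0.0359), matrix enzymes (0.0249), TGF-beta response (0.0469) and cell cycle inhibitors (0.0249) were higher as lists, with 1, 1, 1 and 0 higher members over all genes and 2, 8, 2 and 6 adjusted over the list alone (and 1 inhibitor lower). The call was lost without 12W HFD replicate 1 for macrophage, erythroid and preadipocyte markers (adjusted p = 0.0729 each), without replicates 2 and 3 for macrophage markers (0.0559 and 0.106) and TGF-beta response (0.0618 and 0.0677), and without replicate 5 for erythroid and preadipocyte markers, matrix enzymes and TGF-beta response (0.069 each). Without replicate 4 all 7 lost it and 1 list passed (macrophage 0.12, endothelial 0.122, erythroid 0.0934, preadipocyte 0.11, the others 0.0865 each). Without 6M replicate 1 it was lost for endothelial (0.0937) and preadipocyte markers (0.271), TGF-beta response (0.369), matrix enzymes and cell cycle inhibitors (0.0745 each), and without 6M replicate 2 for macrophage (0.976) and erythroid markers (0.141) and cell cycle inhibitors (0.0737). In all, 4 lists passed without 12W HFD replicate 5 and 5 without 6M replicate 1. In 9 lists the test and the raw median or mean differed in sign, among them the BMP, imprinted, lymphocyte and cholesterol lists, which had positive medians and a downward test. The count of 138 genes became 70 without 12W HFD replicate 1.

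The difference of the KO effect between diets and 3W was tested as an interaction. Of all genes 0 passed at 12W HFD (limma, 419 with unadjusted p under 0.05), although 7 passed without KO 12W HFD replicate 2 and 5 without WT 12W HFD replicate 1. At 1W HFD 1 gene passed (413 with unadjusted p under 0.05), Ighv2-6-8 (adjusted p = 0.00808); the count was 2 without KO 3W replicate 2 or WT 1W HFD replicate 2, and 5 or 12 without KO 1W HFD replicate 1 or 2. The average KO effect over the 3 settings, a contrast chosen after seeing the data, passed for 0 genes (limma, 766 with unadjusted p under 0.05), and 13 lists passed with the preset and 0 with an estimated correlation.

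ATAC-seq gave 123130 accessible regions, of which 35747 were present in all 9 libraries. The 4 groups differed in which regions were open (pseudo-F = 2.026, exact permutation p = 0.0111), which did not hold for peaks with −log10 q of at least 5 (1.933, exact permutation p = 0.0516). Libraries of the same group shared more regions (Jaccard index 0.671 ± 0.051, 6 pairs) than libraries of different groups (0.611 ± 0.054, 30 pairs). Libraries with the same code letter of peak names also shared more (0.657 ± 0.042) than others (0.585 ± 0.047), and a split by letter gave a pseudo-F of 2.832 (exact permutation p = 0.0119).

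At 3W, 3667 regions were gained and 62 lost in KO cells, and 1079 and 294 when every library was held to the same number of peaks. The Jaccard index between KO and WT libraries (0.626 ± 0.051, 6 pairs) differed from that among WT libraries (0.639 ± 0.047, 3 pairs) by less than the spread. Gained regions included an interval within Csgalnact1, a chondroitin sulphate enzyme gene (chromosome 8, 68519613 to 68521237). A lost region lay 1670 bp from Osgep (chromosome 14, 50903303 to 50904808). Within 50 kb of Tcf21 the KO libraries had 8 and 7 regions and the WT libraries at 3W 10, 4 and 5. Within 50 kb of Pparg, the master regulator of adipocyte formation, KO had 18 and 16 and WT 12, 12 and 11. The counts near Dlk1 were 13 and 12 against 13, 11 and 11, and near Cebpa 13 and 13 against 12, 9 and 11. The KO lists were longer (84876 and 78643 peaks against 77862, 55990 and 58675). With equal peak numbers the counts were 5 and 5 against 8, 4 and 5 near Tcf21, 15 and 9 against 10, 12 and 11 near Pparg, 9 and 9 against 12, 11 and 11 near Dlk1, and 9 and 9 against 11, 9 and 11 near Cebpa. The letters were not balanced, since 1 of 2 KO and 2 of 3 WT libraries were of letter B. Leaving out 1 library gave 4520 to 14389 gained and 119 to 613 lost regions.

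After 1W HFD, 8228 regions were gained and 385 lost relative to 3W (3739 and 1065 with equal peak numbers), and after 12W HFD 11959 and 757 (4561 and 2051). All 4 HFD libraries were of letter A and 2 of 3 WT 3W libraries of letter B. Within letter A, with 1 library at 3W, 11370 were gained and 9044 lost at 1W and 15110 and 10808 at 12W. With equal peak numbers as well these were 7663 and 6847, and 8132 and 9191, where the excess at 12W turned to losses. Between 1W and 12W HFD 4893 were gained and 3359 lost, and with equal peak numbers 2331 and 3236, where the excess turned to losses. A region 1906 bp from Cx3cl1, a chemokine for monocytes (chromosome 8, 94784333 to 94790211), was gained after 12W HFD. A region 40603 bp from the growth factor receptor gene Igf1r (chromosome 7, 67909758 to 67912224) was lost. Leaving out 1 library gave 9284 to 20256 gained and 518 to 1359 lost regions at 1W, 13083 to 20969 and 907 to 2058 at 12W, and 6540 to 12171 and 5453 to 12930 between them; with fewer libraries these counts can only rise.

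**Figure D3:**
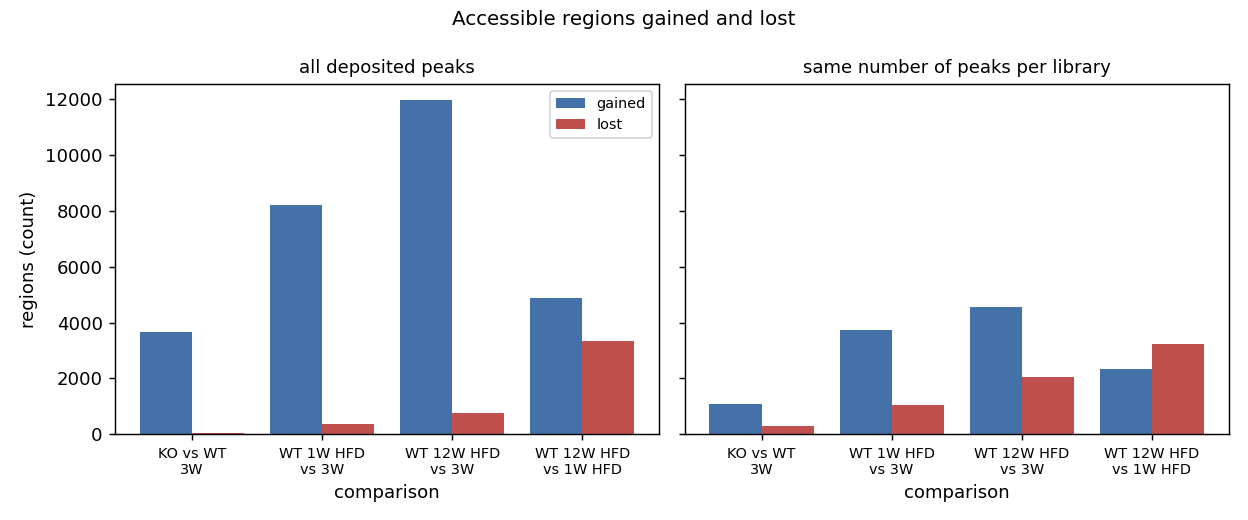
Number of accessible regions gained (blue bars) and lost (red bars) in each comparison (horizontal axis), counted with all deposited peaks (left) and with the same number of peaks per library (right). Gains exceeded losses in all bars but those of 12W HFD against 1W HFD with equal peak numbers (2331 and 3236).

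Genes that rose in RNA-seq lay near gained regions more often than uncalled genes. After 1W HFD, 61.2% of 748 higher genes had a gained region within 50 kb, against 45.2% of uncalled genes (odds ratio 1.91; two-sided Fisher's exact test, adjusted p = 3.36e-17), and 7.3% of 509 lower genes had a lost region, against 2.2% (3.52; adjusted p = 1.87e-09). Lower genes had a gained region less often (0.70; adjusted p = 0.000217), and for higher genes and lost regions the odds ratio was 0.67 (adjusted p = 0.264). After 12W HFD the odds ratios were 2.02 for higher genes and gained regions (66.6% against 49.6%; Fisher's exact test, adjusted p = 1.19e-29) and 2.78 for lower genes and lost regions (13.6% against 5.4%; adjusted p = 7.64e-20), with 0.70 (1.61e-07) and 0.60 (0.00152) for the opposite pairs. Between 1W and 12W HFD they were 2.57 (1.07e-24) and 2.23 (2.69e-13), with 0.99 (adjusted p = 1) for lower genes and gained regions and 0.49 (2.46e-10) for higher genes and lost regions. Among 20 macrophage markers the 12W HFD libraries had a region at 14 and 18 genes and the other libraries at 7 to 10; with equal peak numbers these were 9 and 11, and 7 to 9. Fisher's tests count genes, not libraries. KO was not tested this way, since 0 genes were called.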

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

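All tests of explanations in this part, and all counts of other splits, were chosen only after the result was seen.

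Macrophage markers were higher in WT cells at 6M, after 1W HFD and after 12W HFD than at 3W, in cells sorted for the Tcf21 lineage. The authors' scaling of the columns was argued against, since the lowest median log2 change of the list over these comparisons was 2.22 after median-ratio rescaling. Macrophages or their RNA among the sorted cells may account for the pattern, although the sort should remove such cells. That at least 16 of 20 markers were higher in each comparison restates the pattern and cannot decide this. Accessible regions left this open, since with equal peak numbers the lower of the 12W HFD libraries had a region at 9 of 20 macrophage genes, within the range of the other libraries. A change of the lineage cells stays open too and was not tested, as age, diet, perhaps dosing age and group go together.

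Tcf21 was lower but present in KO libraries. A swap between KO and WT libraries at 3W was argued against, since the KO library had less Tcf21 in 6 of 6 pairings. Cells that kept the gene and a transcript left after the deletion cannot be told apart here: the lowest KO library at 3W still had 46.0% of its WT partner, and TPM per gene does not show which part of the gene was read. No biological explanation was tested.

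More regions were gained than lost in KO cells at 3W. A batch marked by the first letter of the peak names could contribute, since the split of the 5 libraries that parts the letters gave 5797 gained and lost regions and the real split 3729. List length cannot be told apart from a KO effect: with equal lengths gained over lost was 3.67. With 1 KO and 1 WT list (letter A) equal lengths hold the ratio near 1 (1.33). The effect of the KO stays open.

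Other splits of the same libraries were counted for the RNA-seq comparisons of at least 3 against 3 libraries, 100 splits each. For KO against WT at 3W the real split gave 0 genes, so the 100 of 100 splits with as many decide nothing. At an unadjusted p under 0.05 it gave 546 genes, and 93 of 100 splits gave as many. The highest other gave 56 genes past the threshold, which points to a structure among the libraries; the splits took no account of the pairs in the titles. Only the real split had as many genes for 1W HFD against 3W (1257, highest other 540). So it was for 12W HFD against 3W (2220, 974) and 12W against 1W HFD (928, 462). This argues against chance if libraries are independent. For ATAC-seq the splits are too few for a share under 0.05; the real values and highest others were 3729 and 5797 for KO, 8613 and 6832 for 1W HFD, 12716 and 6111 for 12W HFD, and 8252 and 3303 for 12W against 1W HFD.

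Single libraries stood apart from the rest of their group in 16 of 196 tests by Dixon's ratio, where chance gives about 1 in 20. KO 3W replicate 1 was lowest of 5 in BMP genes (3.96 log2 units), cell cycle inhibitors (5.09) and immediate early genes (6.35), and highest in Pparg (79.4 TPM). WT 3W replicate 2 was highest of 7 in Acta2 (1845 TPM) and skeletal muscle markers (3.0 log2 units), and WT 3W replicate 7 in the lipid droplet gene Plin1 (48.0 TPM). WT 1W HFD replicate 2 was highest of 4 in Schwann cell markers (1.5 log2 units) and Wnt genes (3.76), replicate 3 in pericyte markers (3.59), and replicate 4 had the lowest column sum (948266 TPM). WT 12W HFD replicate 1 was lowest of 5 in TGF-beta response genes (4.76 log2 units) and highest in chemokines (6.73), replicate 2 was lowest in Dlk1 (listed at 0) and mesothelial markers (1.36), and replicate 4 was highest in Igf2 (1.1 TPM).

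The KO effect differed between 12W HFD and 3W, by the interaction with camera's preset correlation, for macrophage markers (adjusted p = 2.2e-16; adjusted p = 0.0394 with an estimated correlation), immediate early genes (3.96e-08; 0.412), chemokines (7.9e-08; 0.28), lymphocyte markers (6.89e-06; 0.28), interferon response (2.41e-05; 0.574), Dpp4-type markers (2.43e-05; 0.412), cell cycle genes (0.00227; 0.755) and committed preadipocyte markers (0.0148; 0.414), both p given in that order. Without KO 12W HFD replicate 1 the call was lost for cell cycle genes (adjusted p = 0.471), committed preadipocyte markers (0.0924), chemokines (0.085) and immediate early genes (0.0729). Cell cycle genes lost it too without KO 3W replicate 1 (0.646), interferon response without WT 12W HFD replicate 1 (0.182), and preadipocyte markers without KO 3W replicate 2 (0.135), WT 3W replicate 6 (0.064) and WT 12W HFD replicates 2 and 3 (0.156 and 0.0501). Between 1W HFD and 3W it differed for mesothelial markers (0.00038; 0.58), erythroid markers (0.000411; 0.58), cell cycle genes (0.000411; 0.828), Dpp4-type markers (0.00215; 0.828) and collagens (0.00979; 0.828), and for the single gene Ighv2-6-8 (limma adjusted p = 0.00808). Without KO 1W HFD replicate 1 the call was lost for Dpp4-type markers (adjusted p = 0.391), collagens (0.128) and mesothelial markers (0.613). Dpp4-type markers lost it too without KO 3W replicate 1 (0.0521) and WT 3W replicate 2 (0.0524), and cell cycle genes without KO 3W replicate 2 (0.0593) and KO 1W HFD replicate 2 (0.333, in the other direction). Collagens lost it without KO 3W replicate 4 (0.0745), WT 3W replicates 2 and 3 (0.231 and 0.079) and WT 1W HFD replicates 2 and 3 (0.0631 and 0.116).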

How the results depend on the processing

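The macrophage covariate, the average of KO comparisons, leaving out WT 3W replicates 1 and 2, letter A alone, rescaled columns, equal peak numbers near named genes and with the RNA calls, the test within pairs, the block with equal peak numbers, regions that went opposite ways in the pairs and list tests without 1 library were chosen only after the result was seen.

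Among the single genes followed across settings, 4027 values kept their direction and side of the threshold, 492 lost the threshold, 4 gained it and 4 turned. Read depth is unknown, so what a low or listed 0 TPM can exclude is unknown too, which bears on the KO genes at 1W and 12W HFD. Except where a construction is named, the cause was not tested. Counts are genes past the threshold unless regions are named.

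With no filter, KO at 1W HFD had 11 genes, KO at 12W HFD 22, and the interactions 9 (12W HFD) and 8 (1W HFD). With at least 5 TPM these were 1 and 0, and 0 for the interaction at 1W HFD. A pseudocount of 0.1 gave 0 for KO at 12W HFD, 90 for 12W HFD against 6M and 0 for the interaction at 1W HFD. Median-ratio scaling gave 6 for KO at 12W HFD and 4 lists for 12W HFD against 6M; quantile scaling gave 5 for KO at 12W HFD, 85 for 12W HFD against 6M and 2 for the interaction at 1W HFD. Array weights gave 8 for KO at 12W HFD, 43 for 3W against P12, 1937 for 1W HFD against 3W, 1882 for 12W against 1W HFD and 2 for the interaction at 1W HFD. A fit of the compared groups alone, with fewer libraries for the spread, gave 15 for KO at 1W HFD, 0 for KO at 12W HFD, 59 for 3W against P12, 686 for 6M against 3W, 730 for 1W HFD against 3W, 0 for 12W HFD against 6M and 8 for the interaction at 1W HFD.

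With a macrophage covariate, which follows the groups by construction, KO at 1W HFD had 2 genes, KO at 12W HFD 0, 6M against 3W 3, 1W HFD against 3W 5, 12W HFD against 3W 1 and 12W against 1W HFD 5. It turned Igf2 in KO at 3W (0.02), Tyrobp at 6M (-0.33) and after 12W HFD (-0.04), and Ccl8 after 12W HFD (-0.09). The average KO effect, a contrast of its own that counts no single diet, passed for 0 genes (limma, 766 with unadjusted p under 0.05). Without WT 3W replicates 1 and 2, KO at 3W had 1 gene.

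Lists past the threshold fell with an estimated correlation from 9 to 0 for KO at 3W, 8 to 0 at 1W HFD, 11 to 0 at 12W HFD, 12 to 0 for 3W against P12, 18 to 5 for 6M against 3W, 15 to 2 for 1W HFD and 18 to 7 for 12W HFD against 3W, 10 to 2 for 12W against 1W HFD, 8 to 0 for 12W HFD against 6M, and 8 to 1 and 5 to 0 for the interactions at 12W and 1W HFD. With 1 library left out, the number of lists ranged from 6 to 12 for KO at 3W, 5 to 10 at 1W HFD, 9 to 11 at 12W HFD, 7 to 14 for 3W against P12, 15 to 19 for 6M, 12 to 16 for 1W HFD and 15 to 19 for 12W HFD against 3W, 8 to 11 for 12W against 1W HFD, 1 to 11 for 12W HFD against 6M, and 5 to 10 and 4 to 8 for the interactions. Of 122 list calls 62 were lost without at least 1 library, and 50 other lists passed without one. With the block, 2 more lists passed for KO at 3W and 3 were lost.

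The replicate block used the pair numbers of the titles at 3W and elsewhere bare replicate numbers, which name no pairs. At 3W, 5 of 5 KO and 5 of 6 WT libraries correlated best with their own number, a hint from the data. The block gave 0 genes for KO at 3W, KO at 1W HFD, KO at 12W HFD, 3W against P12, 6M against 3W, 1W HFD against 3W and 12W HFD against 6M, 1455 for 12W HFD against 3W and 280 for 12W against 1W HFD, with fewer libraries and 1 to 5 residual degrees of freedom. In ATAC-seq, the block within pairs 1 and 2 gave 4520 gained and 382 lost regions in KO, where 3075 and 238 would be expected if the pairs were independent, and 1715 and 918 with equal peak numbers (882 and 517 expected). Regions gained in pair 1 and lost in pair 2 numbered 566, and the reverse 1193 (542 and 1349 expected). With equal peak numbers these were 876 and 698 (691 and 661 expected), so regions that went opposite ways also exceeded independence there. Pair 1 lies within letter A and pair 2 within letter B, so the block balances the letter.

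In groups of 2 libraries (KO 1W and 12W HFD, P12, 6M) the lone library left is assumed to vary like the other groups, in list tests too. Leaving out 1 library at a time gave 0 to 2 genes for KO at 3W, 2 to 28 at 1W HFD, 0 to 14 at 12W HFD, 177 to 420 for 3W against P12, 778 to 1860 for 6M and 665 to 1556 for 1W HFD against 3W, 1774 to 2375 for 12W HFD against 3W, 678 to 1059 for 12W against 1W HFD, 70 to 194 for 12W HFD against 6M, and 0 to 7 and 1 to 12 for the interactions at 12W and 1W HFD. Tcf21 in KO ranged from -1.13 to -0.74 at 3W, -1.18 to -0.24 at 1W HFD and -1.92 to -0.59 at 12W HFD. Regions gained and lost ranged from 4520 to 14389 and 119 to 613 for KO, 9284 to 20256 and 518 to 1359 for 1W HFD, 13083 to 20969 and 907 to 2058 for 12W HFD, and 6540 to 12171 and 5453 to 12930 for 12W against 1W HFD, counts that can only rise with fewer libraries. The pseudo-F ranged from 1.636 to 2.478.

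Peaks with −log10 q of at least 5 gave 1731 gained and 40 lost regions in KO, 238 lost at 1W HFD and 496 at 12W HFD, and a pseudo-F of 1.933 (exact permutation p = 0.0516). Equal peak numbers gave 1079 and 294 in KO, 3739 and 1065 at 1W HFD, 4561 and 2051 at 12W HFD, 2331 gained for 12W against 1W HFD, and an odds ratio of 0.57 for higher genes and lost regions at 1W HFD. Letter A alone, with fewer libraries, gave 18349 and 8049 in KO, 11370 and 9044 at 1W HFD and 15110 and 10808 at 12W HFD; with equal peak numbers as well these were 8753 and 6557, 7663 and 6847, and 8132 and 9191.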
